A study of Homo sapiens with 6 samples.

How the data were processed

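Per the labels' protocols, RNA was isolated from human breast cancer cells with a column kit and libraries were prepared with standard Illumina protocols; selection of polyadenylated RNA, strand and read length were not given in the sources used here. The series holds 6 samples of 1 cell line, 3 control and 3 treated with recombinant mouse Ccl2 (10 nM) and Ccl7 (50 nM) for 6 hours. Groups were taken from the sample titles.

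The deposited table gives 1 value per gene and library for 19863 human Ensembl genes. The values match RPKM: they are not whole numbers, and among low genes the ratios between libraries are ratios of whole numbers times 1 constant per pair of libraries. No header says whether reads or read pairs were counted, so the authors' deposited RPKM values could equally be FPKM. Per the submitters' processing notes, TopHat2 2.0.7 and DESeq2 were used, and the genome builds named there are the mouse builds GRCm38 and mm10. The gene identifiers and chromosomes of the deposited table are human, so the build that the authors aligned to is open. The counting tool, the annotation release and the formula of the values were not given in the sources used here. No authors' comparison was used, and no column of per-sample values was left out.

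Reads were recovered from the RPKM values by finding, for each gene, the whole numbers whose ratios matched those between libraries within 0.01 reads. A fallback for genes with too many reads for this search used the annotated length and a wider tolerance. This gave whole reads for 100% of the 16760 genes above 0 in at least 1 library. Reads are known only up to a whole multiple, chosen to give the annotated length or else a whole number of bases. Whole lengths are thus largely by construction, and were not checked for genes with few reads. The implied lengths equalled the exon-union length in GENCODE v29 for 8310 of the 16600 genes with an annotated length (within 0.01 base). The recovered reads added up to 99.7% of the depth implied for each library. Depth and recovered reads are reconstructions, used for the precision of low values, for replicate comparison and for 1 alternative test. A count of 0 allows up to 3 reads in a library, and such limits cover counting error only. Gene symbols are those of the table, where 165 symbols occur for more than 1 Ensembl identifier. List members are counted by identifier, so that IRF9, UQCR11, NDUFB8, SDHD and HIST2H2AA4 each count as 2. Coordinates were taken by Ensembl identifier from GENCODE v29 (GRCh38), which holds 19570 of the 19863 identifiers; the 293 others, AL049872.1 among them, have none here.

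The main test was limma 3.58.1 in R 4.3.3 (eBayes with trend, two-sided) on log2(RPKM + 1), over 11138 genes with a mean of at least 1 RPKM over the 6 libraries, with group as the only term and Benjamini-Hochberg adjustment, threshold 0.05. The design written before the data were examined covered counts and normalized values. Since the deposited unit is RPKM, its form for normalized values was used for the main test; limma-voom on the recovered reads, fitted beside it, was the only count-based test. With 3 samples against 3, an exact permutation test of a single gene cannot go below p = 0.1, so single genes rest on the spread that limma pools across genes.

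A set of 23 gene lists was fixed before the data were examined: ligands, receptors and the gene in the line's name, immediate early, ERK feedback, NF-kB and inflammatory cytokine, interferon-stimulated, STAT3 and SOCS, hypoxia and glycolysis, cholesterol synthesis, ATF4 and unfolded protein response, heat shock, cell cycle, p53 target, epithelial and mesenchymal, protease and invasion, YAP target, Hedgehog, stem-cell, luminal, basal, fibroblast, leukocyte, mitochondrially encoded and ribosomal protein genes. The lists share some genes. Those with at least 5 tested members, 18 in all, were tested against all other tested genes with camera (limma, preset correlation 0.01), with Benjamini-Hochberg adjustment over the 18 lists. Camera with a correlation estimated from the data and fry, which tests whether the genes of a list move on balance 1 way, were run beside it. Estimated correlations rest on 4 residual degrees of freedom and are imprecise, and the p-values of that form of camera rest on the same 4. The estimate was below the preset 0.01 for immediate early (-0.034), ERK feedback (-0.023), interferon-stimulated (-0.029) and heat shock (-0.028) genes. The larger p of these lists in that form therefore does not come from correlated members. For NF-kB (0.061), ribosomal protein (0.071), mitochondrially encoded (0.38) and YAP target genes (0.41) the estimate was above it. Another 7 lists were written after the genes with the largest changes had been seen, and their p-values were adjusted over these 7 alone. They held TGF-beta and SMAD targets, serum response factor targets, NRF2 targets, and fatty acid synthesis and nuclear-encoded respiratory chain genes. The others held genes of mitochondrial replication, transcription and RNA processing with their regulators, and replication-dependent histones.

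Named genes followed a rule fixed at the same time. It took the 12 largest rises and 12 largest falls in log2 fold change among genes past the threshold whose groups did not overlap and whose mean was at least 5 RPKM; FOXC1, CCL2, CCL7, CCR1, CCR2 and CCR3; up to 4 tested members of each list with the smallest p; and the 5 most abundant genes of each library. Some genes that the rule takes are not reported here. SREBF2 and MT-ND3 in the report were chosen after their values were seen.

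The test was tried on simulated reads for treated against control, drawn from the real means and depths with 200 genes changed. Over 11151 genes, it called 62% of genes changed 1.2-fold and 100% of those changed 1.5-fold, 2-fold or 4-fold. Of 10953 unchanged genes 11 were called, which was 5.8% of all calls. In the same simulation camera called a list of 20 raised genes and did not call a list of 20 unchanged genes. Genes were drawn independently, with a fixed dispersion of 0.0005. The simulation therefore cannot show how often camera makes false calls where members of a list move together.

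Alternatives were other pseudocounts (0.1 and 5), no minimum level or 5 RPKM, the replicate number as a block, fold thresholds, each library left out in turn, and, chosen after the data were seen, a 2-fold threshold, median-ratio scaling, leaving out the mitochondrial genes, limma-voom on the recovered reads, 1 identifier per symbol in the lists (the one with the higher mean), and removal of a loess trend (span 0.3) of the fold changes with GC content and length. The GC and length correction was first run without centring and was then changed to keep the median fold change, after its output had been seen. GC content came from the GENCODE v29 transcripts and was found for 99.3% of the tested genes.

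These choices can affect the measurements. RPKM scales each library to its own reads, so a group of abundant genes that rises lowers all others. Reads shared between near-identical genes could be split in a way that the table does not show, which concerns CXCL1, CXCL2 and CXCL3, HSPA1A and HSPA1B, ribosomal protein genes with their pseudogenes, and mitochondrial genes with their nuclear copies. Reads of overlapping or antisense genes cannot be told apart without strand. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for recovery, and matplotlib 3.10.9 for figures.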

Results

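RNA was measured by sequencing in MDA-MB-231-FOXC1 cells. MDA-MB-231 is an established human triple-negative breast cancer line grown from metastatic cells. The labels do not say what the suffix FOXC1 stands for beyond the name of that gene, which encodes a forkhead transcription factor. The treated group, 3 samples, received recombinant mouse Ccl2 at 10 nM and Ccl7 at 50 nM for 6 hours. The control group, 3 samples, is labelled as control. No time is given for the controls, so whether they were matched to the treated samples in time is open. CCL2 and CCL7 are chemokines, secreted proteins that attract monocytes through the receptors CCR2, CCR1 and CCR3. The deposited table holds 19863 human genes with 1 value per library on the RPKM scale, that is, reads per kilobase of gene, scaled to the reads counted in the library.

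Whole read numbers could be recovered from the values, which gave the depth of each library. The 3 control libraries held 14358703, 14572938 and 15127004 counted reads, and the 3 treated libraries 14143607, 19838009 and 15629525. Between 11061 and 11169 genes per library reached 1 RPKM. Libraries of the same group differed slightly more than counting noise, with a mean chi-square per gene of 1.28 to 1.37 over the 6 pairs within groups, so none was treated as a copy of another. The 9 pairs between groups gave 12.6 to 14.8. Nothing in the labels says that the 3 samples of a group came from separate cultures. The titles number the controls Cntl1 to Cntl3 but carry Control-1 in all 3, which leaves open whether these are repeats of 1 sample. All p-values therefore measure only the spread between these samples, which may be technical. Levels are given as mean RPKM ± SD over the 3 libraries of a group, and fold changes as log2 differences, treated minus control, on the log2(RPKM + 1) scale, which understates the change of low genes.

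The comparison asked how the transcriptome differed between cells given Ccl2 and Ccl7 for 6 hours and control cells. Among the largest rises, EDN1, the precursor of the vasoconstrictor endothelin, went from 17.9 ± 0.343 to 44.2 ± 1.41 RPKM (2.47 times as high, n = 3 libraries per group), and CXCL8, the neutrophil chemokine interleukin-8, from 269 ± 1.29 to 517 ± 2.01. The steepest falls were those of DDIT4, an inhibitor of mTORC1 signalling (44.5 ± 0.427 to 12.1 ± 0.679 RPKM), PTGES, a prostaglandin E synthase (31.4 ± 1.18 to 9.41 ± 0.566), and C3, the central complement component (21.2 ± 0.305 to 6.60 ± 0.0915). Enzymes of cholesterol synthesis rose as a group, and the 13 protein-coding genes of the mitochondrial genome rose, although as a list these missed the threshold with an estimated correlation (adjusted p = 0.0989 in camera).

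Of 11138 genes with a mean of at least 1 RPKM, 4983 passed an adjusted p of 0.05 in limma (two-sided), 1918 of them higher and 3065 lower in the treated cells. Most changes were small, with a median absolute log2 fold change of 0.20 among these genes. On the log2(RPKM + 1) scale only 174 changed by at least 1.5-fold, 65 up and 109 down, and 16 by at least 2-fold, 7 up and 9 down. That scale understates fold changes, as with MYO18A, which fell to 0.480 of its control RPKM and is not among the 9. The 3 treated values lay entirely above or entirely below the 3 control values for 54.5% of the tested genes (6071). Chance gives 10% if the 6 libraries are independent samples, which the labels leave open. Genes that fell made up 61.5% of the calls on the deposited scale. After median-ratio scaling, a setting chosen after the data were seen that centres the fold changes, they made up 50.1%. How far falls outnumbered rises therefore depends on the scaling.

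The 12 largest rises among genes with a mean of at least 5 RPKM and no overlap between the groups included EDN1 (ENSG00000078401; GRCh38 chromosome 6, 12290363 to 12297194, protein coding), with a log2 fold change of 1.26 (SE 0.03, adjusted p = 1.7e-09 in limma). HMGCS1, the cytosolic HMG-CoA synthase, followed with 1.13, and HHIP, a membrane protein that binds and restrains Hedgehog ligands, with 1.11. TRIML2 and ADAMTS1, a secreted metalloprotease, rose by 1.08 and 1.04. CXCL8 rose by 0.94, CXCL3, a related chemokine, by 0.87, MSMO1, an enzyme of sterol synthesis, by 0.86, CSF2, the cytokine GM-CSF, by 0.85, and NOG, the BMP antagonist noggin, by 0.84. Adjusted p-values of these genes in limma lay between 2.4e-11 for CXCL8 and 7.2e-05 for CSF2. Another of them, AL049872.1, had a log2 fold change of 2.80 that rests on few reads: 5 in the controls, all in control 1, and 38 in the treated libraries. Without control 1 its log2 fold change was 3.70, and it ranged from 1.41 to 4.98 with other pseudocounts, all past the threshold.

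DDIT4 (ENSG00000168209; GRCh38 chromosome 10, 72273920 to 72276036, protein coding) fell by 1.80 on the log2 scale (SE 0.04, adjusted p = 5.4e-10 in limma), the largest fall by the same rule. PTGES fell by 1.64 and C3 by 1.54. CSF3, the cytokine G-CSF, fell by 1.10, so the genes of GM-CSF and G-CSF moved in opposite directions. CEBPD, a transcription factor of the acute-phase response, fell by 1.05. The other falls were those of MYO18A, an unconventional myosin (-0.96), MARCKSL1, an actin-binding protein (-0.90), JUP, the junction protein plakoglobin (-0.89), KCTD12 (-0.88), OTUB2, a deubiquitinase (-0.86), CLIP2, a microtubule-binding protein (-0.85), and OASL, an interferon-induced gene (-0.83). Adjusted p-values of these 12 genes in limma lay between 5.4e-10 for DDIT4 and C3 and 3.6e-06 for JUP.

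**Figure D1:**
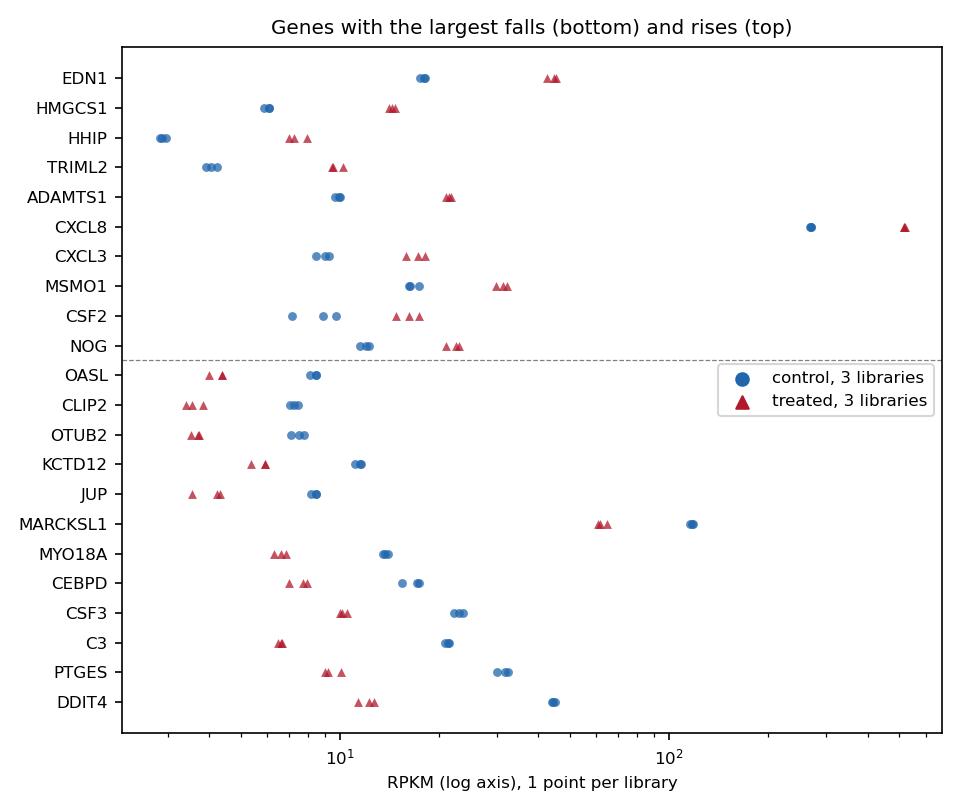
Levels in RPKM (log axis) of 22 of the genes with the largest rises (above the dashed line) and falls (below it), 1 point per library, with blue circles for the 3 control and red triangles for the 3 treated libraries. AL049872.1 is left out because 2 of its control values are 0. In every gene shown the 3 treated values lie on 1 side of the 3 control values, because the rule that chose the genes required it. The means for DDIT4, for example, were 44.5 RPKM in control and 12.1 in treated cells.

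FOXC1 (ENSG00000054598; GRCh38 chromosome 6, 1609972 to 1613897) stood at 68.7 ± 1.06 RPKM in control and 91.1 ± 1.76 RPKM in treated cells, 1.33 times as high (log2 fold change 0.40, SE 0.02, adjusted p = 6.2e-07 in limma). The values do not separate reads of the endogenous gene from those of any introduced copy. CCL2 and CCL7 had 0 reads in each of the 6 libraries, which allows at most 0.151 to 0.212 CPM in a library (3 reads, counting error only). CCR2 had 1 read in total, in control 1, and CCR3 had 1, 6 and 4 reads in the controls and 3, 5 and 3 in the treated libraries, so no difference in either was detectable at this depth. CCR1 had 10, 11 and 21 reads in the controls and 1, 6 and 6 in the treated libraries, 0.347 ± 0.1405 against 0.0924 ± 0.0595 RPKM. It lay under the minimum for testing. With no minimum, its log2 fold change was -0.30 (SE 0.07, adjusted p = 0.0217 in limma).

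Cholesterol synthesis genes rose almost without exception. Of 19 tested members 18 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change of 0.58. HMGCS1 went from 6.03 ± 0.132 to 14.4 ± 0.303 RPKM, MSMO1 from 16.7 ± 0.629 to 31.0 ± 1.19, INSIG1, the sterol-sensing regulator of the pathway, from 24.1 ± 0.641 to 41.9 ± 1.03, and FDFT1, squalene synthase, from 27.3 ± 0.460 to 39.3 ± 0.843. SREBF2, the transcription factor that drives these genes, was at 25.02 ± 0.580 and 25.3 ± 0.573 RPKM and did not pass (adjusted p = 0.752 in limma). The list passed camera with an adjusted p of 3.8e-17 and was the 1 list of 18 that also passed with an estimated correlation (adjusted p = 0.0127).

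The table holds the 13 protein-coding genes of the mitochondrial genome and none of its rRNA and tRNA genes. All 13 rose, also when adjusted over the list alone, with a median log2 fold change of 0.65. They took 1.87% ± 0.0138 of the counted reads in control and 2.87% ± 0.0272 in treated libraries (SD, n = 3 libraries). MT-CO1, a subunit of cytochrome c oxidase, rose from 2013 ± 28.8 to 3507 ± 25.5 RPKM and MT-ND1, a subunit of complex I, from 1387 ± 4.29 to 2375 ± 29.1. MT-CO2 and MT-ND4 rose 1.39-fold and 1.57-fold. MT-ND3 rose least, 1.05-fold, and its call was lost once a trend with GC content and length was removed (adjusted p = 0.372 in limma). The list passed camera (adjusted p = 7.3e-22), with adjusted p = 0.0989 with an estimated correlation.

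**Figure D2:**
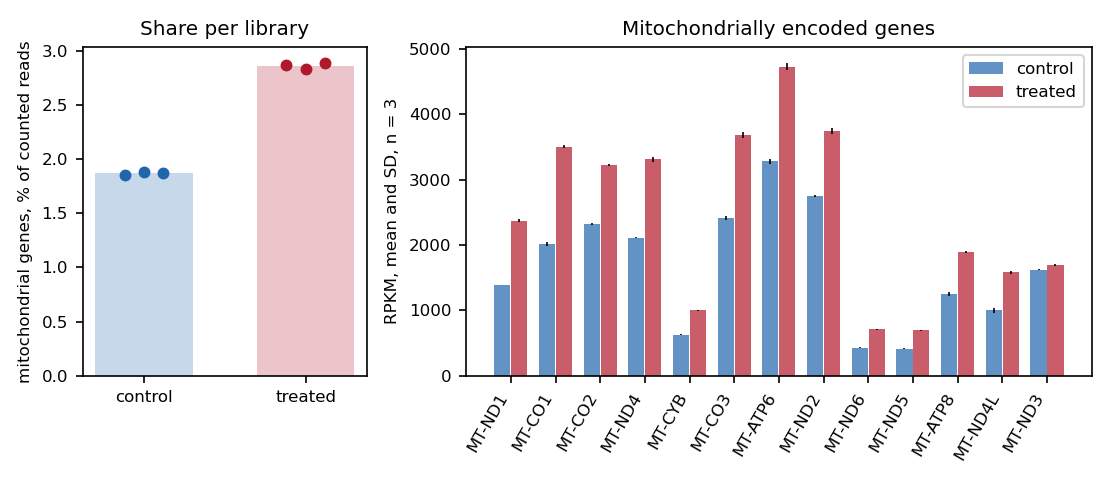
Left, percent of counted reads in the 13 mitochondrially encoded genes, with 1 point per library and the group mean as a bar. Right, mean RPKM of each of the 13 genes in control (blue) and treated (red) libraries, with the SD of 3 libraries as error bars. The share was 1.87% in control and 2.87% in treated libraries, and the change was smallest for MT-ND3, at 1.05-fold.

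NF-kB target and inflammatory cytokine genes shifted upward, with exceptions. Of 21 tested members 12 rose and 5 fell, also when adjusted over the list alone, with a median of 0.18. CXCL8 and CXCL1 rose, the latter from 126 ± 2.12 to 196 ± 5.11 RPKM, and TNFAIP3, a feedback inhibitor of NF-kB, rose from 4.05 ± 0.0630 to 7.78 ± 0.325. IL1B, the cytokine interleukin-1 beta, fell from 80.7 ± 0.630 to 46.6 ± 0.940 RPKM. The adjusted p in camera was 0.00222, with adjusted p = 0.141 with an estimated correlation.

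Among immediate early genes, the first transcription factors induced by growth signals, FOSL1 rose from 125 ± 2.96 to 164 ± 0.663 RPKM, JUN from 59.5 ± 1.27 to 74.2 ± 1.304 and EGR1 from 3.70 ± 0.447 to 5.22 ± 0.249, while JUND fell from 57.4 ± 0.334 to 43.8 ± 0.641. Of 12 tested members 6 rose and 1 fell (7 and 2 adjusted over the list alone), with a median of 0.10 (0.03 with no minimum level) and a camera adjusted p of 0.0274. Without control 2, 5 rose and 2 fell. The call was lost with an estimated correlation (adjusted p = 0.141), with no minimum level (adjusted p = 0.166) and with a minimum of 5 RPKM (adjusted p = 0.0967).

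ERK feedback genes, a list of genes induced by ERK signalling of which some restrain it, moved down. Of 16 tested members 9 fell and 2 rose (10 and 2 adjusted over the list alone), with a median of -0.21. Only 1 rose without control 1, control 2, treated 2 or treated 3 and with no minimum level. The phosphatase genes DUSP4 and DUSP5 fell from 68.8 ± 0.458 to 47.0 ± 0.436 RPKM and from 54.6 ± 1.99 to 40.3 ± 0.662, PHLDA1 from 74.7 ± 0.496 to 59.4 ± 0.466, and ETV5 from 25.2 ± 0.448 to 17.9 ± 0.747. In camera the list had an adjusted p of 0.0144, with adjusted p = 0.14 with an estimated correlation.

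Interferon-stimulated genes fell as well. Of 20 tested identifiers 11 fell and 1 rose (12 and 2 adjusted over the list alone), with a median of -0.21 (-0.12 with a pseudocount of 5 and -0.13 with no minimum level). None rose without control 1, treated 2 or treated 3, 3 rose after median-ratio scaling, and 7 of 13 fell with a minimum of 5 RPKM. IRF9 has 2 of these identifiers, of which 1 was the rise (adjusted p = 0.0340 in limma, and 0.0925 for the other). With 1 identifier per symbol, a setting chosen after the data were seen, the median of the 19 genes was -0.25. OASL fell from 8.35 ± 0.181 to 4.26 ± 0.215 RPKM, ISG15, a ubiquitin-like protein, from 62.4 ± 1.90 to 48.6 ± 1.14, IFIT2 from 13.4 ± 0.677 to 8.89 ± 0.444, and DDX58, the RNA sensor RIG-I, from 18.0 ± 0.446 to 14.2 ± 0.151. Camera gave an adjusted p of 0.00616, and adjusted p = 0.14 with an estimated correlation.

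Of 15 tested YAP target genes 6 rose and 5 fell, also when adjusted over the list alone, with a median of 0.03. The number that fell was 3 without control 1, without treated 3 and with the mitochondrial genes left out, and after median-ratio scaling 7 rose and 3 fell. The median was 0.08 without control 1, 0.02 without control 2 and 0.06 after median-ratio scaling or with a minimum of 5 RPKM. ANKRD1 rose from 249 ± 4.42 to 438 ± 3.68 RPKM, CTGF, a matricellular growth factor, from 275 ± 4.50 to 452 ± 1.51, F3, tissue factor, from 118 ± 1.10 to 165 ± 1.05, and CYR61 from 335 ± 2.94 to 388 ± 1.31. Camera gave an adjusted p of 0.0292 upward, and adjusted p = 0.515 with an estimated correlation. The call was also lost without control 2 (adjusted p = 0.0622) and with no minimum level (adjusted p = 0.0662).

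Heat shock genes showed small shifts. Of 13 tested members 8 rose and 3 fell, also when adjusted over the list alone, with a median of 0.07. The chaperone genes HSPA8, HSPE1 and HSPA1B rose 1.10-fold, 1.19-fold and 1.17-fold, while HSPB1, a small heat shock protein, fell from 100.4 ± 3.58 to 78.1 ± 0.936 RPKM. Camera gave an adjusted p of 0.0184, and adjusted p = 0.14 with an estimated correlation. Of 39 ribosomal protein genes 27 rose and 6 fell (28 and 6 adjusted over the list alone), with a median of 0.09 (0.06 with the GC content and length trend removed), yet the 4 with the smallest p all fell. RPLP0 fell from 846 ± 12.3 to 673 ± 3.46 RPKM, RPS2 from 1880 ± 7.71 to 1565 ± 21.9, RPLP1 from 470.0 ± 1.71 to 377 ± 6.51 and RPSA from 336 ± 0.218 to 290 ± 0.824. By camera the list passed upward (adjusted p = 1.4e-05), with adjusted p = 0.14 with an estimated correlation.

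**Figure D3:**
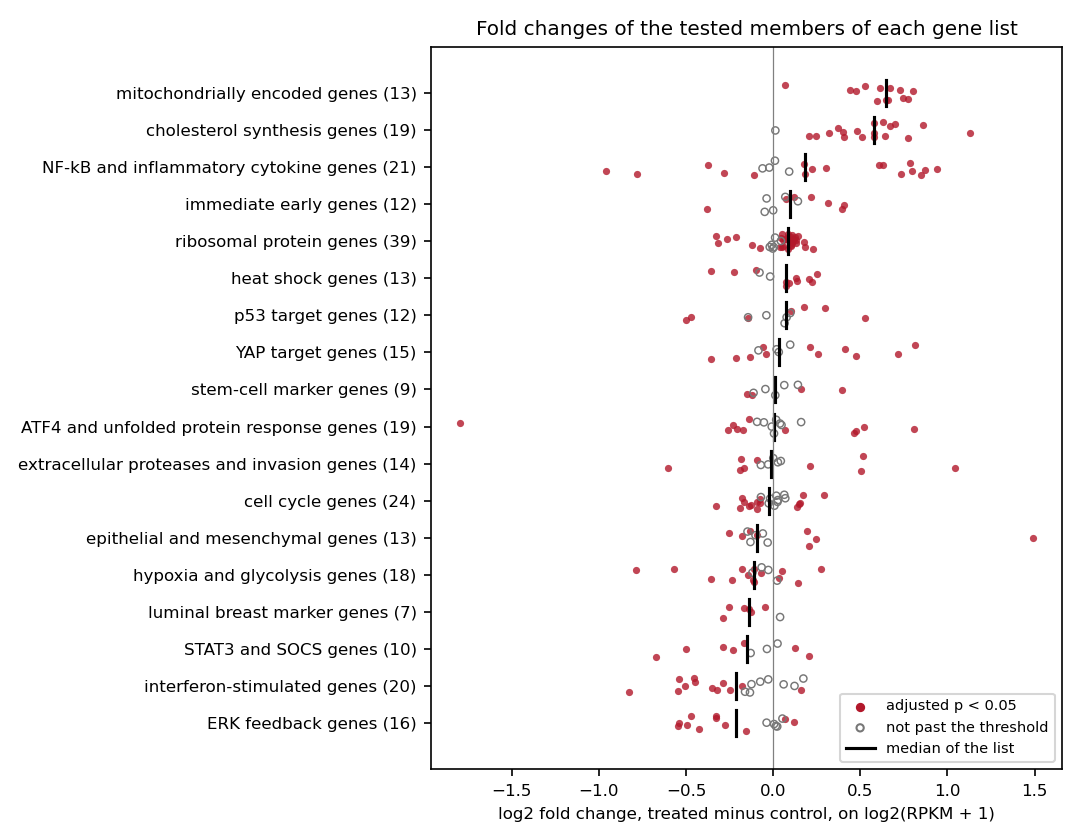
Log2 fold changes of the tested members of the 18 gene lists with at least 5 tested genes, 1 point per gene, with the number of tested members after each name. Filled red points passed an adjusted p of 0.05 and open points did not, and black bars mark list medians, from 0.65 for mitochondrially encoded genes to -0.21 for ERK feedback genes.

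The other 9 tested lists did not pass camera. All of them passed fry except the ATF4 and unfolded protein response genes (adjusted p = 0.594 in fry). Of 18 hypoxia and glycolysis genes 10 fell and 4 rose, also when adjusted over the list alone (adjusted p = 0.0660, median -0.11, and -0.07 with a minimum of 5 RPKM), and the list passed without treated 3 (adjusted p = 0.0472) and with limma-voom on the recovered reads (adjusted p = 0.00793). Among them VEGFA, the angiogenic growth factor, fell from 4.82 ± 0.209 to 2.38 ± 0.107 RPKM, NDRG1 from 4.37 ± 0.134 to 2.62 ± 0.0475, LDHA, lactate dehydrogenase, from 252 ± 0.815 to 214 ± 4.10, and GAPDH from 2135 ± 11.1 to 1977 ± 19.5. Of 10 STAT3 and SOCS genes 5 fell and 2 rose (6 and 2 adjusted over the list alone; adjusted p = 0.196; median -0.15, and -0.08 with no minimum level). The cytokine signalling inhibitors SOCS1 and SOCS2 fell from 7.11 ± 0.319 to 4.09 ± 0.161 and from 5.52 ± 0.0768 to 3.62 ± 0.3196 RPKM, BCL2L1 fell to 0.849 of its control level, and the receptor gene IL6ST rose 1.16-fold.

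Genes of the ATF4 and unfolded protein response went both ways, with 5 of 19 higher and 6 lower (6 and 6 adjusted over the list alone; adjusted p = 0.522 upward), and their median of 0.005 and mean of -0.02 differed in sign. Leaving out 1 library gave medians from -0.02 to 0.02, and median-ratio scaling gave 0.03. SLC7A11 and SLC3A2, the subunits of the cystine transporter, rose from 13.3 ± 0.368 to 24.1 ± 0.205 and from 41.1 ± 0.630 to 59.5 ± 0.397 RPKM, whereas DDIT4 and the chaperone gene HSPA5 fell, the latter from 137 ± 1.80 to 118 ± 0.980. Of 12 p53 target genes 4 rose and 3 fell (5 and 3 adjusted over the list alone; median 0.07, adjusted p = 0.283, and adjusted p = 0.00706 among the 6 with a mean of at least 5 RPKM). The number that fell was 1 without control 2, 2 without any other single library or after median-ratio scaling, and 0 with a minimum of 5 RPKM, and the median was -0.04 with no minimum level, 0.04 with a pseudocount of 5 and 0.14 with a minimum of 5 RPKM. GADD45A rose from 25.9 ± 0.924 to 37.8 ± 0.783 RPKM and PLK3 from 4.68 ± 0.145 to 6.00 ± 0.318, and PHLDA3 and GDF15 fell to 0.519 and 0.652 of their control levels.

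Cell cycle genes showed no common direction in camera, whereas fry called them lower (adjusted p = 0.0169 in fry). Of 24 tested, 5 rose and 10 fell (5 and 11 adjusted over the list alone; median -0.02, adjusted p = 0.805), and after median-ratio scaling 8 rose and 8 fell with a median of 0.01. Leaving out 1 library gave medians from -0.04 to -0.0054, and removing the GC content and length trend gave -0.06. AURKB and UBE2C, which act in mitosis, rose 1.22-fold and 1.13-fold, while the survivin gene BIRC5 and the replication gene MCM3 fell to 0.792 and 0.876 of their control levels.

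Among epithelial and mesenchymal genes 4 of 13 rose and 4 fell (4 and 5 adjusted over the list alone; adjusted p = 0.522 upward, and adjusted p = 0.0120 with limma-voom). Their median was -0.09 (-0.03 with a minimum of 5 RPKM, -0.04 with a pseudocount of 5 and -0.06 after median-ratio scaling) and their mean 0.08. The mesenchymal filament gene VIM rose from 1399 ± 4.98 to 1599 ± 8.90 RPKM and FN1, fibronectin, from 15.8 ± 0.439 to 18.9 ± 0.313, and TGFBR2 fell from 46.4 ± 1.32 to 40.8 ± 0.895. Of 14 genes of extracellular proteases and invasion 4 rose and 5 fell, also when adjusted over the list alone (adjusted p = 0.522 upward), with a median of -0.01, which was 0.01 after median-ratio scaling, 0.03 with no minimum level and -0.0061 to -0.03 with 1 library left out, and a mean of 0.07. The collagenase gene MMP1 rose from 357 ± 3.16 to 511 ± 5.54 RPKM, ADAMTS1 from 9.87 ± 0.164 to 21.4 ± 0.354, and PLAUR, the urokinase receptor, from 15.6 ± 0.564 to 22.5 ± 0.342. TIMP3, an inhibitor of metalloproteases, fell from 28.6 ± 0.944 to 18.5 ± 0.460 RPKM.

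Of 9 stem-cell marker genes 2 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.482). Their median of 0.01 had no stable sign: it was 0.04 without control 1, -0.0041 without control 2, -0.01 without treated 3 and -0.01 with no minimum level, and leaving out 1 library gave 1 to 3 rises and 1 or 2 falls. CD44, a hyaluronan receptor, rose from 42.5 ± 0.564 to 56.3 ± 0.438 RPKM and ITGA6 fell to 0.899 of its control level. HES1 rose 1.14-fold and BMI1 fell to 0.918 of its control level, but each lost its call without control 3 or without treated 1 (adjusted p = 0.0799 and 0.108 for HES1, 0.0575 and 0.0533 for BMI1, limma). HES1 also lost it without control 2 (0.110) or treated 2 (0.0725), with no minimum level (0.0655), with limma-voom (0.0795) and with the GC content and length trend removed (0.0865), and BMI1 after median-ratio scaling (0.0567). Among 7 luminal breast markers 6 fell and 0 rose, also when adjusted over the list alone (adjusted p = 0.0660, and adjusted p = 0.0242 without control 3; median -0.14, and -0.09 with no minimum level). The number that fell depended on single libraries: it was 2 of 6 without control 2, 3 of 6 without control 1, 3 of 7 without treated 2 and 4 of 7 after median-ratio scaling, and 3 of 10 with no minimum level. The keratin genes KRT18 and KRT19 fell to 0.913 and 0.891 of their control levels, and ERBB3 and MUC1 to 0.668 and 0.786. ERBB3 lost its call without treated 2 (adjusted p = 0.0570 in limma) or treated 3 (0.0613), and MUC1 with no minimum level (0.0616) and without control 2 (0.0817), control 3 (0.0603) or treated 1 (0.0745).

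The remaining 5 lists had fewer than 5 tested members and no list test, and counts adjusted over the list alone were equal to those over all genes. Among Hedgehog genes HHIP rose from 2.89 ± 0.0630 to 7.39 ± 0.475 RPKM, and SUFU, GLI3 and GLI2, which encode a pathway inhibitor and transcription factors, fell to 0.713, 0.775 and 0.748 of their control levels, giving a median of -0.23 (-0.38 with limma-voom) and a mean of 0.06. The GLI2 call was lost without control 1 (adjusted p = 0.0796 in limma), treated 1 (0.0606) or treated 3 (0.0781). Of 4 basal breast markers 2 rose, FOXC1 among them, and 1 fell. ITGB4, an integrin of hemidesmosomes, fell from 3.56 ± 0.184 to 1.25 ± 0.0725, and EGFR was at 32.7 ± 0.449 and 33.1 ± 0.297 (adjusted p = 0.611 in limma, and 0.0339 with the GC content and length trend removed). Their median was 0.21 and their mean -0.04. Markers of other cell types were few at this level: of the fibroblast genes COL1A1 alone was tested, at 1.998 ± 0.0549 and 1.86 ± 0.121 RPKM (adjusted p = 0.325 in limma). Of the leukocyte genes, CD68 was at 119 ± 1.02 and 118 ± 1.77 RPKM (adjusted p = 0.424 in limma) and LAPTM5 fell from 6.11 ± 0.442 to 4.99 ± 0.516, a call lost without control 1 (adjusted p = 0.0573 in limma). FOXC1 was the single tested member of the list of ligands, receptors and the gene in the line's name.

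Of the 8 genes that were among the 5 most abundant of any library, 5 were mitochondrial. MT-ATP6 stood at 3282 ± 34.0 RPKM in control and 4734 ± 59.8 in treated cells, and MT-ND2 and MT-CO3 rose 1.36-fold and 1.53-fold. FTL, the ferritin light chain, fell from 2813 ± 23.4 to 2480 ± 28.8 RPKM, and ACTB, cytoplasmic actin, rose from 2489 ± 11.2 to 2672 ± 18.8. TMSB10 fell to 0.979 of its control level (adjusted p = 0.0445 in limma), a call that was lost after median-ratio scaling (0.899), with the mitochondrial genes left out (0.238), with no minimum level (0.159) and without control 1 (0.136), control 2 (0.0653), control 3 (0.0669), treated 2 (0.0595) or treated 3 (0.120).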

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

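Settings described as chosen after the data were seen are median-ratio scaling, leaving out the mitochondrial genes, limma-voom, the GC content and length correction, 1 identifier per symbol and the 2-fold threshold. The count of 4983 genes past the threshold in limma stayed between 3809 (minimum of 5 RPKM, with fewer genes tested) and 5488 (limma-voom) under every setting but the fold thresholds. At least 1.5-fold on the log2(RPKM + 1) scale left 174 genes, 65 higher and 109 lower. At least 2-fold on that scale left 16, 7 higher and 9 lower, since most changes are small. Leaving out 1 library gave 4238 to 4398 genes, 1616 to 1691 higher and 2622 to 2721 lower, where fewer samples lower the power. Of the 18 lists, 9 passed camera, 1 with an estimated correlation and 17 by fry, which asks a different question; leaving out 1 library gave 8 to 10, and 1 identifier per symbol 9. The labels do not say whether equal replicate numbers mark paired samples. Deviations of same-numbered libraries correlated at 0.05, 0.01 and 0.01, and samples 1 correlated best with their own number while samples 2 and 3 did not. These values cannot decide on pairing. Spread within groups was close to counting noise (mean chi-square per gene 1.28 to 1.37), so correlations would be small even between paired samples. With the replicate block, 4827 genes and 9 lists passed. Over 105 named genes and all settings, 1550 comparisons gave 1521 with the direction and side of the threshold as reported, 28 that lost the call and 1 that gained it, and no called gene or list changed direction with a call on both sides. Most of these genes were named for a small p or a large change in the main test, so kept calls were likely beforehand. Of all 4983 calls, 4083 were also made without treated 2, 4401 after median-ratio scaling and 4653 with the replicate block. The cause of single lost calls was not tested. The planned count-based alternatives (edgeR with other scalings, DESeq2) were not run, because the unit is RPKM. Depth limits CCR1, CCR2, CCR3 and AL049872.1, which rest on few reads.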

Other observations

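The lists in this paragraph and the next, and the single genes named in them, were chosen after the genes with the largest changes had been seen, so their tests are not independent of those changes. Adjusted p-values of these lists are over 7 lists, not over the 18 fixed beforehand. Of 25 tested TGF-beta and SMAD target genes, 16 rose and 3 fell (5 with limma-voom), with a median log2 fold change of 0.21 (camera adjusted p = 2.9e-07, and adjusted p = 0.0254 with an estimated correlation). IGFBP3 rose 1.69-fold, FST, the activin inhibitor follistatin, 1.58-fold, ID3 1.27-fold and SKIL, a feedback inhibitor of SMAD signalling, 1.34-fold, whereas BMP4 fell to 0.768 of its control level. Of 17 tested NRF2 target genes 13 rose and 2 fell, with a median of 0.20 (camera adjusted p = 9.1e-07, and adjusted p = 0.0968 with an estimated correlation). HMOX1, heme oxygenase, rose 1.93-fold, TXNRD1, thioredoxin reductase, 1.49-fold and NQO1 1.35-fold, while the ferritin genes FTL and FTH1 fell to 0.881 and 0.930 of their control levels.

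Fatty acid synthesis genes did not pass as a list: of 14 tested, 6 rose and 4 fell (camera adjusted p = 0.339). SCD rose 1.195-fold, ACACA fell to 0.826 of its control level, and SREBF1, the transcription factor of that pathway, fell from 35.4 ± 0.233 to 20.7 ± 0.658 RPKM. HIF1A and EPAS1, the oxygen-regulated transcription factors, fell from 45.1 ± 0.351 to 27.1 ± 0.601 and from 13.4 ± 0.324 to 8.03 ± 0.169 RPKM. Within the NF-kB list BCL3 fell to 0.432 of its control level while BIRC3 and CXCL2 rose 1.83-fold and 1.77-fold. Of 16 serum response factor targets 5 rose and 6 fell (camera adjusted p = 0.539). Of 19 genes of mitochondrial replication, transcription and RNA processing with their regulators 4 rose and 2 fell (camera adjusted p = 0.339). Among 75 identifiers of 72 nuclear-encoded respiratory chain genes 11 rose and 13 fell (camera adjusted p = 0.376). Among 18 replication-dependent histone genes 2 rose and 3 fell (camera adjusted p = 0.855). These counts depend on the scaling: after median-ratio scaling 17 respiratory chain identifiers rose and 6 fell, and 8 serum response factor targets rose and 4 fell. In that setting 7 genes of mitochondrial replication, transcription and RNA processing rose and 2 fell, and 2 histone genes rose and 2 fell.

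In the paragraphs that follow, the tests of depth, of handling, of scaling and of MT-ND3 were chosen after the result was seen. The real grouping gave 4983 genes and the highest of the other splits of the 6 libraries gave 0 in limma (130 to 174 genes at an unadjusted p under 0.05). Only 1 of the 10 splits gave as many genes as the real one, but 10 splits are too few for a share under 0.05. Each other split puts treated and control libraries in both of its groups, so the difference between treated and control inflates its spread. Few or no calls were therefore fixed beforehand, and the splits cannot show whether chance gave the real count.

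The 13 mitochondrially encoded protein-coding genes rose together with a median of 0.65, while the 75 identifiers of nuclear-encoded respiratory chain genes had a median of 0.0031 over a range from -0.29 to 0.22, which argues against a rise of the whole respiratory chain. Depth is argued against, since the deepest and the shallowest treated library differed in mitochondrial share by 2.84% of the difference between groups. With the GC content and length trend removed the median was 0.58 and 12 of the 13 genes kept their call, although the bound set beforehand asked for all 13; MT-ND3 went from 0.07 (SE 0.01) to -0.011 (SE 0.01), so that its small rise may be such a trend. Capture of RNA with short tails stays open, because the histone genes that could show it (median -0.081, SD 0.31) lay below the bound set beforehand but had a median of only 22.3 reads per library, too few to decide. Handling of cultures or libraries cannot be told apart from the treatment, since the share varied by 0.0543 percentage points within the treated libraries and no sample of either group is known to have been handled apart.

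Genes that fell outnumbered those that rose on the deposited scale, at 61.5% of the calls. With the mitochondrial genes left out and the libraries rescaled the share was 56.4%, so the larger mitochondrial share may account for part of the excess, while the bounds set beforehand (45 to 55%, or above 58%) leave this undecided. Median-ratio scaling gave 50.1%, but it centres the fold changes and so fixes the share. Spearman's rho of the fold changes with GC content was -0.0431, within the range set beforehand (-0.05 to 0.05), which counts against GC content, but that range left out length, where rho was -0.123, and the correction for both gave 61.7% when it kept the median fold change and 50.7% when it did not, an outcome set by centring that leaves length open. Whether more genes fell per cell cannot be told apart from scaling in these values.

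The rise of the cholesterol synthesis genes had a median of 0.58 and was the 1 list, of the 18 fixed before the data were examined, that passed camera with an estimated correlation. With the GC content and length trend removed the median was 0.57, which argues against that trend as its cause. Median-ratio scaling shifts all genes nearly alike, by 0.033 on the log2 scale, so a median near its value of 0.60 was fixed beforehand. That value shows only that the shift between these 2 scalings is small beside the rise. No biological explanation was tested beyond the treatment itself. A difference in medium, time in culture or handling between the groups stays open, as the design holds no sample that would separate it from the chemokines.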
